A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

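Ribosome footprints of budding yeast were measured by selective ribosome profiling of Ssb, an Hsp70 chaperone that binds nascent chains at the ribosome. Each of 4 mixed cultures held a strain with GFP-tagged Ssb1, without SSB2 and without 1 further gene (TAL1, PMT1, RTN1 or BAT1), together with untagged cells described as wild type. Per the labels' protocols, cells were collected by filtration, frozen and lysed by milling. Ribosomes were then pelleted through sucrose, and each pellet was divided into a total part and a part purified through the GFP tag (selected). This gave 8 libraries, 4 total and 4 selected, with 1 mixture per deletion. The labels do not say that a mixture was repeated, so the 4 mixtures served as the replicates of selected against total. P-values of single genes and of the position along the coding sequence measure the spread between these mixtures. Those of gene lists set the genes of a list against the other genes. Those of the deleted genes come from reassigning the deletions to the mixtures.

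The deposited values are RPM: per the file headers and the values themselves, the authors gave footprint reads normalised to the library's total for each nucleotide and strand of the 16 nuclear chromosomes. Each read had been spread evenly over several neighbouring nucleotides. Adapters were removed with cutadapt 1.11, per the submitters' processing notes. The aligner, the read-length filter and the handling of reads with several matches are not given in the sources used here. Chromosome lengths in the files equalled those of assembly R64, and gene positions came from the RefSeq table of that assembly, with strand taken from the systematic name. This table gave 6002 nuclear protein-coding genes and no introns, so the span of an intron-containing gene included its intron. The list of mitochondria-encoded proteins is not analysed here.

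RPM was summed over each coding sequence on its own strand, leaving out 58368 nucleotides shared by 2 coding sequences on 1 strand (138 genes). Depth was recovered from the smallest steps in each file and ran from 4408143 to 10546780 reads. Between 1280 and 1974 genes per library were listed at 0. No gene free of overlap lay above 0 with fewer than 64 reads, which is 6.07 to 14.5 RPM depending on the library, so a gene listed at 0 may have had reads below that level. Signal outside coding sequences was 0.0948% to 0.237% of the total. Reads recovered per gene were whole numbers, within 0.02 reads, for 10.3% to 26.9% of genes, so the planned count tests were not run.

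For each deleted gene, its selected level in its own mixture was divided by the mean of the other 3 mixtures, and the result was divided by the same ratio of total levels. This index is 0 when no ribosome of the untagged cells was recovered, and 1 when selected and total held the same share of them. The 4 genes together were tested with a one-sided exact permutation test over the 24 assignments of deletions to mixtures, whose smallest possible p is 0.0417. Intervals of 95% on single ratios used the recovered reads and cover counting error alone. Background subtraction was not run, because URA3, LEU2 and MET17, deleted by genotype in both strains, were listed at 0. HIS3, deleted by genotype as well, had reads in every library. Profiles along the deleted genes used 20-codon windows, and each mixture was compared with the mean of the other 3. They were set against 596 genes of 600 to 3000 nucleotides with at least 150 RPM.

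Enrichment across genes was tested with limma 3.58.1 in R 4.3.3 on log2(RPM + 1), with the mixture as a block, for 4177 genes with a mean of at least 10 RPM. Benjamini-Hochberg adjusted p under 0.05 was required. Fold changes are on the log2(RPM + 1) scale, which understates the change of low genes. Selected and total libraries of 1 mixture came from the same pellet, per the labels' protocols. Their deviations from the group means correlated across genes at 0.303 to 0.536 within a mixture and at -0.387 to 0.148 between mixtures. Gene lists were tested with camera from limma with a preset correlation of 0.01, for 23 lists with at least 5 measured members, and again with an estimated correlation. Enrichment along the coding sequence was the mean log2 ratio of selected to total density in codons 1 to 30 minus that in codons 61 to 200, over 1503 genes of at least 250 codons and at least 50 RPM in every library. It was tested over the 4 mixtures with a two-sided exact sign-flip permutation test. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.

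Groups, tests, gene lists, the alternatives marked as planned and the rule for named genes were fixed before the data were examined. The profile comparison, the test on the start of the deleted genes and several alternatives were added after the values had been seen. Named genes were the 4 deleted genes, the genes set by the genotype or related to a deleted gene, and the 12 highest and 12 lowest genes by log2 enrichment. Those 24 had to pass the threshold, reach a mean of 50 RPM and have the same direction in all 4 mixtures. Ribosomal protein genes were left out of them, and so were genes whose symbol is only a systematic name, as a stand-in for transposon genes and dubious reading frames. From each list the highest and lowest measured member with at least 50 RPM and up to 2 further abundant members were taken, and some of these are not reported here.

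On simulated data, the limma step recovered 35 of 100 genes changed by 0.5 and 83 of 100 changed by 1 on the log2 scale, and called 0 unchanged genes among 4111 tested. A simulated index of 0.5 was estimated at 0.502, and a simulated start difference of -0.5 at -0.463 over 1503 genes. Alternatives covered scaling, pseudocounts of 0.1 and 5 RPM, filters, the first 50 and last 5 codons left out, the block, and each mixture left out.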

Results

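Footprints were collected from 4 mixed yeast cultures, each with 1 total and 1 selected library. Selected libraries hold what was purified through the GFP tag of Ssb1, and total libraries hold all ribosomes of the same pellet. The deleted genes below show that selected libraries also hold ribosomes of untagged cells. Selected over total is therefore not a measure of Ssb binding in the cell alone. The total libraries had 6237919, 7011768, 7229032 and 9396340 reads in the tal1, pmt1, rtn1 and bat1 mixtures, and the selected libraries had 4408143, 10546780, 6283608 and 6245991. The mixtures were made as a control for chaperone binding after lysis. A gene deleted in the tagged strain can give footprints in its own mixture only from untagged cells, whose ribosomes should reach the selected library only if they were captured after the cells were broken.

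Footprints of all 4 deleted genes were present in the selected library of their own mixture, at a lower level than in the other mixtures. BAT1, a mitochondrial branched-chain aminotransferase (YHR208W, chromosome VIII, 517532 to 518713, R64), had 525 RPM in its own selected library against 1305 ± 132 RPM in the others (SD, n = 3). PMT1, a protein O-mannosyltransferase of the ER (YDL095W, chromosome IV, 287059 to 289512), had 168 RPM against 535 ± 73.9. RTN1, a reticulon of the tubular ER (YDR233C, chromosome IV, 929470 to 930357), had 189 RPM against 361 ± 48.6. TAL1, the transaldolase of the pentose phosphate pathway (YLR354C, chromosome XII, 836350 to 837357), had 484 RPM against 817 ± 82.4.

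The total libraries were lower for the deleted genes too. In its own total library TAL1 had 726 RPM against 1144 ± 140.1 RPM in the others (SD, n = 3), and BAT1 had 531 against 942 ± 78.5. PMT1 had 191 against 333 ± 55.7, and RTN1 had 232 against 350 ± 33.8. Own total levels were thus 63.5%, 57.4%, 66.4% and 56.4% of the other mixtures for TAL1, PMT1, RTN1 and BAT1, and own selected levels were 59.2%, 31.4%, 52.5% and 40.2%. The index of selected over total was 0.932 for TAL1, 0.548 for PMT1, 0.791 for RTN1 and 0.714 for BAT1, with a mean of 0.746 ± 0.160 (SD over 4 genes). The genotype markers URA3, LEU2 and MET17 were listed at 0 in all 8 libraries, while HIS3, also deleted by genotype, was not.

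On the log2 scale, selected over total of BAT1 was -0.02 in its own mixture (95% counting interval -0.08 to 0.05) and 0.47 ± 0.03 in the others (SD, n = 3). PMT1 was at -0.18 (-0.29 to -0.08) against 0.69 ± 0.28, and RTN1 at -0.30 (-0.40 to -0.19) against 0.04 ± 0.29. The lowest RTN1 ratio among the other mixtures was -0.2954, against -0.2955 in its own. For RTN1 a ratio this low was thus not particular to the mixture with the deletion. TAL1 was at -0.59 (-0.66 to -0.51) against -0.48 ± 0.03. Among 1803 genes, 0 had as low a difference in the bat1 mixture as BAT1, 3 in the pmt1 mixture as PMT1, 35 in the rtn1 mixture as RTN1 and 351 in the tal1 mixture as TAL1. Over the 4 genes the mean difference was -0.45, the lowest of the 24 assignments (one-sided exact permutation p = 0.0417, the smallest the design allows). ER membrane proteins as a list were also lower in the mixtures of PMT1 and RTN1, by list medians of -0.45 and -0.20. Relative to proteins of the same compartment the index was 0.746 for PMT1, 0.909 for RTN1, 0.918 for TAL1 and 0.708 for BAT1, a comparison chosen after the values were seen. No single deletion has a replicate mixture, and 3 mixtures cannot give a p below 0.167.

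**Figure D1:**
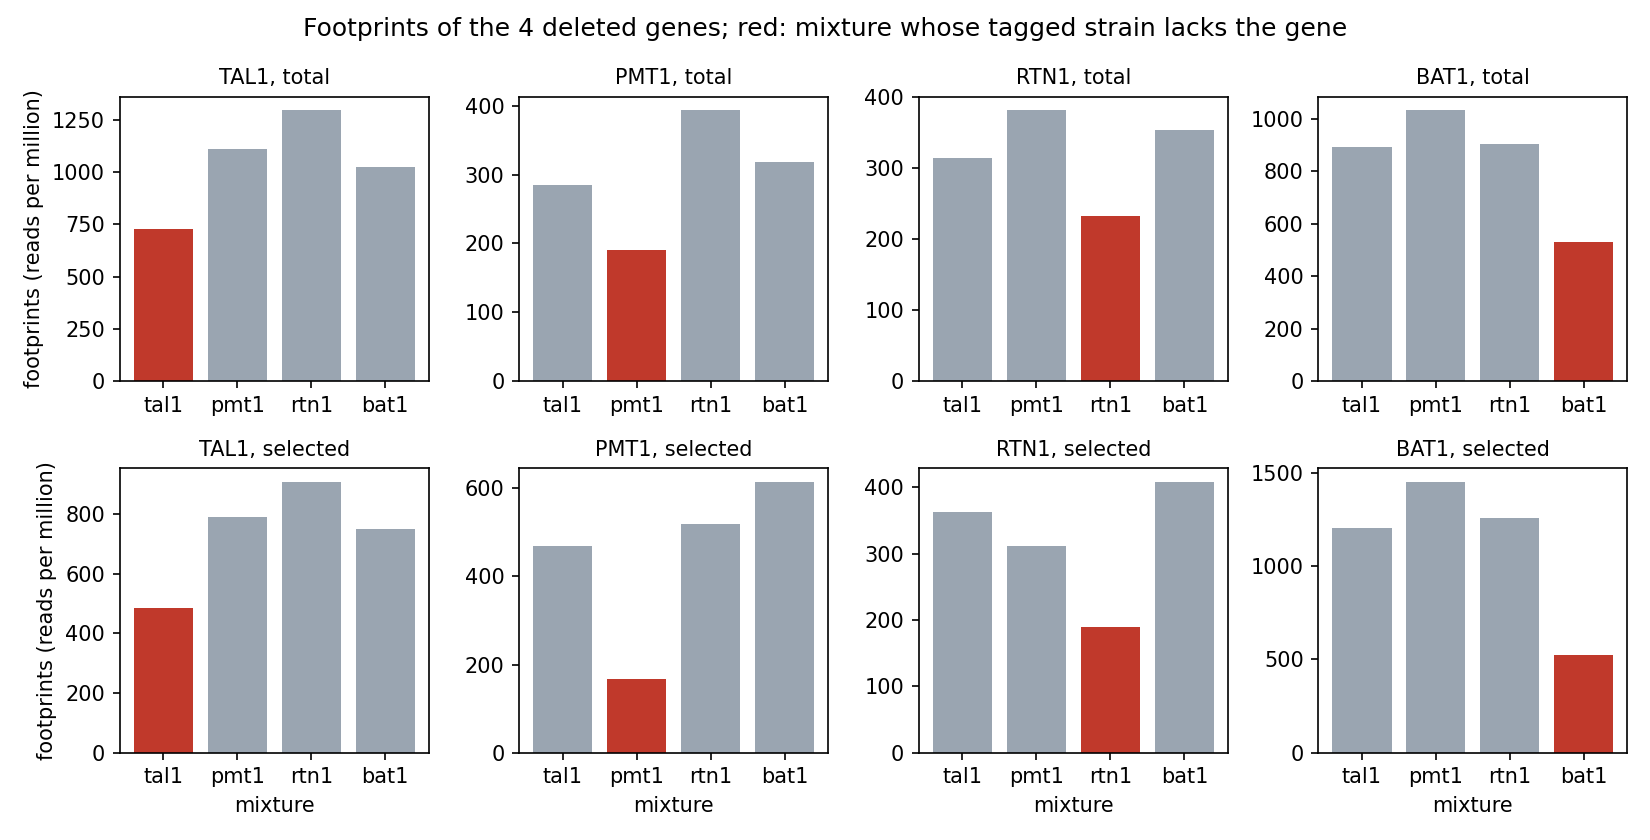
RPM of TAL1, PMT1, RTN1 and BAT1 in the total and selected libraries of the 4 mixtures, as bars, 1 library each, with the gene's own mixture in red. In the selected libraries the own mixture lies below the others for each gene, for example 525 RPM against a mean of 1305 RPM for BAT1.

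Along the deleted genes, the pattern of selected over total in the own mixture differed from that in the other mixtures. In codons 121 to 140 of BAT1 the log2 ratio was 1.00, 1.26 and 1.29 in the other mixtures and -0.54 in its own. In codons 221 to 240 of TAL1 it was 0.47, 0.40 and 0.12 against -0.30, and in codons 41 to 60 it was -1.69, -1.39 and -1.20 against -0.47. The correlation with the mean profile of the other mixtures, across windows of a gene, was 0.54 for TAL1, 0.68 for PMT1, 0.82 for RTN1 and 0.69 for BAT1 in the own mixture. In the other mixtures it ran from 0.95 to 0.96, 0.73 to 0.90, 0.84 to 0.95 and 0.94 to 0.96. Among 596 genes, 5 had as low a difference as TAL1, 29 as PMT1, 24 as RTN1 and 3 as BAT1. The mean difference was -0.219, the lowest of 24 assignments (one-sided exact permutation p = 0.0417, the smallest possible). Without the tal1 mixture the difference was -0.129. Without the first 60 codons it was -0.239 and 2 of 24 assignments were as low (exact permutation p = 0.0833). For each deleted gene the own libraries held the fewest reads, for example 1190 selected reads of RTN1 against 1597 to 3284 in the others. Fewer reads per window can lower a correlation, and the 24 assignments and the 596 genes do not correct for this. The profile comparison was chosen after the values were seen.

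Relative to the rest of the gene, the start of the deleted genes was less depleted in the own mixture than in the others. The start taken alone was not less depleted in each gene. In codons 21 to 40 of PMT1 the log2 ratio was -1.443 in its own mixture and -0.2528, -1.258 and -0.7151 in the others. In codons 41 to 60 of TAL1 it was -0.4651 against -1.691, -1.394 and -1.197. Start windows of RTN1 and BAT1 in the own mixture lay mostly within the range of the others. Codons 1 to 60 minus the rest of BAT1 gave a log2 ratio of -0.99 in its own mixture and -1.50 ± 0.39 in the others (SD, n = 3). For PMT1 the values were -1.16 and -1.62 ± 0.13, for RTN1 -0.69 and -1.19 ± 0.31, and for TAL1 -0.11 and -0.87 ± 0.23. Own minus others was 0.56 ± 0.14 (SD over 4 genes), above 0 for 4 of 4 genes and the furthest from 0 of 24 assignments (two-sided exact permutation p = 0.0417, the smallest possible), a test chosen after the values were seen.

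**Figure D2:**
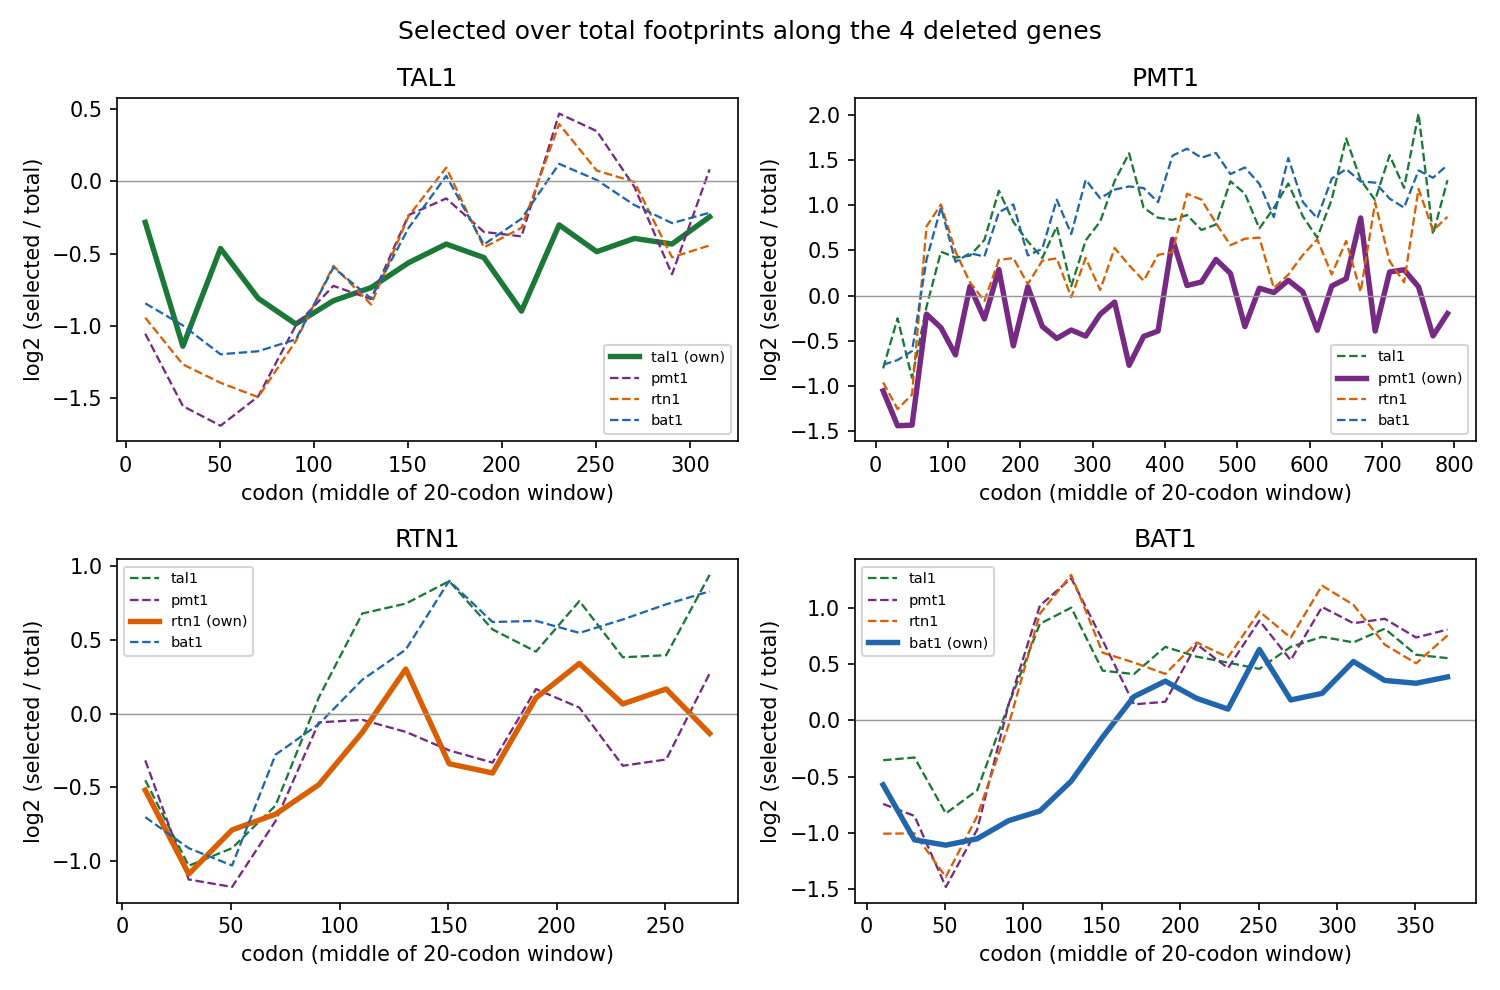
Log2 ratio of selected to total RPM in 20-codon windows along TAL1, PMT1, RTN1 and BAT1, with 1 line per mixture and a thick line for the own mixture. In codons 121 to 140 of BAT1 the own mixture lies at -0.54 and the others between 1.00 and 1.29.

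The genes that carry the tag or are set by genotype were read next. SSB1, the tagged gene (YDL229W, chromosome IV, 44065 to 45906), had 2903 ± 75.1 RPM in total and 3690 ± 314 RPM in selected libraries (SD, n = 4), a log2 ratio of 0.34 ± 0.15. SSB2, absent from the tagged strain (YNL209W, chromosome XIV, 252059 to 253900), had 22.3 ± 2.61 and 31.1 ± 9.34 RPM. SSB2 was 0.502% to 1.03% of SSB1 in the 8 libraries, so the cells described as wild type contributed few SSB2 footprints. SSB1 had no reads at 275 of its 614 codons in any library, and reads shared by these near-identical genes are uncertain. HIS3, deleted by genotype in both strains, had 70.3 ± 20.96 RPM in total and 49.9 ± 16.4 RPM in selected libraries. At codons 102 to 167 it was at 0 in all 8 libraries. Of the relatives of the deleted genes, BAT2 had a log2 ratio of 0.32 ± 0.10 and YOP1, a partner of the reticulons, -0.41 ± 0.18. SSB1 and YOP1 lost their limma call without the rtn1 mixture (adjusted p of 0.0603 and 0.0544). PMT2, the partner of PMT1, was at 0.66, -0.21, 0.22 and 0.80 in the tal1, pmt1, rtn1 and bat1 mixtures. NQM1 and RTN2 were listed at 0 in all libraries.

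The genes highest in the selected libraries had longer coding sequences at the median than the lowest. KCS1, an inositol polyphosphate kinase (YDR017C, chromosome IV, 479115 to 482267), rose from 59.6 to 138 RPM, a log2 change of 1.19 ± 0.10 (SE, 4 pairs; limma adjusted p = 0.00164). MLF3 rose by 1.16, SBE2 by 1.09, the phosphatase PTP3 by 1.08, the polymerase REV1 by 1.05 and the kinase PSK2 by 1.04. RIM101 rose by 1.02, RBS1 and SIS2 by 1.01 each, TOS4 by 0.99, DUR12 by 0.98 and the asparaginase ASP1 by 0.95, from 322 to 633 RPM. UMP1, a proteasome maturation factor (YBR173C, chromosome II, 581726 to 582172), fell by 1.04 ± 0.07 (SE; limma adjusted p = 0.00149), from 85.6 to 41.3 RPM.

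ATP17, the clathrin light chain CLC1 and SRP40 each fell by 1.02, TOM6 by 0.98, RPC10 by 0.97, and SBH2 and TMA7 by 0.94. EGD1, a subunit of the nascent polypeptide-associated complex, fell by 0.93 and DSK2 by 0.91. SOD1, the cytosolic superoxide dismutase, and SNC2 fell by 0.90, SOD1 from 1192 to 646 RPM. By the rule that chose them, each of these 24 genes moved the same way in 4 of 4 mixtures and passed limma's adjusted p. The 12 highest had a median of 745.5 codons and the 12 lowest 132.5, against 449 over all genes tested, and the ranges of 382 to 1836 and 62 to 407 codons overlapped.

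Of 4177 genes, 2290 passed, 1462 higher and 828 lower in the selected libraries, and 30 of them changed by more than 1 on the log2 scale. That last count was 19 without the pmt1 mixture, 15 at a mean of at least 50 RPM, 50 with the median ratio scaled to 1, 49 without the first 50 and last 5 codons and 85 without a filter on low genes. The median gene lay at 0.13. When the median ratio was scaled to 1 it lay at 0.01, and 953 genes were higher and 1057 lower. The share of higher genes among those called was then 47.4% in place of 63.8%, so values near 0 have no settled sign. Without the first 50 and last 5 codons the median gene lay at 0.26, and 2010 genes were higher and 579 lower (77.6% higher). After the scaling ERG11, VMA1, VMA2, YEF3, MRPS18, GGC1, CDC19, OAC1, SSE1, BAT2 and the tagged SSB1 lost their limma call (adjusted p of 0.0544 to 0.186). Without the mixture as a block LEU1, FAS1, ERG11, SSC1, GGC1, OAC1, PET9, BAT2 and HIS3 lost theirs (adjusted p of 0.0638 to 0.718). Without the first 50 and last 5 codons CYS3, SSC1, EFB1, CCW12 and PET9 did (adjusted p of 0.0506 to 0.297). Without a filter on low genes ERG11 and PET9 were not called by limma (adjusted p of 0.0593 and 0.0529), nor was PET9 with a pseudocount of 5 RPM (0.0518) or among genes above 0 in all libraries (0.0670). Relative to the median gene, KCS1 was at 1.06, ASP1 at 0.82, SOD1 at -1.03 and UMP1 at -1.17. Across genes, which are not independent replicates, enrichment correlated between mixtures at 0.740 to 0.894.

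Among the lists tested, ribosomal proteins and histones were most depleted from the selected libraries. Short genes other than those of the ribosome were depleted too. Their median was -0.78 up to 100 codons and -0.34 at 100 to 200 codons. The lists were not compared with genes of like length, so their calls do not separate the group from length. Of 81 large-subunit genes 70 fell, 2 rose and 9 were not called, with a median of -0.57, and adjusted over the list alone 74 fell and 2 rose. Of 56 small-subunit genes 48 fell, 0 rose and 8 were not called, with a median of -0.56 (-0.37 without the first 50 and last 5 codons), and adjusted over the list alone 49 fell and 1 rose. RPL29 fell by 0.98, RPS27A by 0.94 and RPP0 by 0.33, while RPL4B rose by 0.37. All 9 histone genes fell, also when adjusted over the list alone, with a median of -0.78, HHF2 by 0.83 and HTB2 by 0.68. Camera's adjusted p was 4.82e-25 for the large subunit, 2.53e-18 for the small subunit and 9.35e-07 for histones. The adjusted p = 0.252, 0.252 and 0.413 with an estimated correlation. Many of these genes have near-identical copies, so their reads may be shared.

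Cytosolic and ribosome-associated chaperones were lower as a list, with a median of -0.11. Of 19 members 8 fell, 2 rose and 9 were not called, the same adjusted over the list alone (camera adjusted p = 0.00773, adjusted p = 0.413 with an estimated correlation). EGD1 fell by 0.93, SSE1 rose by 0.22, and SSA2 was at 0.21 and HSC82 at -0.06. SSE1 lost its limma call without the rtn1 mixture (adjusted p = 0.0591). Among members with a mean of at least 50 RPM the median was -0.39 (camera adjusted p = 0.00448), and with the median ratio scaled to 1 it was -0.23 (0.00931). Without the first 50 and last 5 codons it was 0.01, while camera still called the list lower than other genes (adjusted p = 0.0115).

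Lipid synthesis enzymes and amino acid biosynthesis were the lists called higher. Of 10 enzymes of cytosolic lipid synthesis 7 rose, 0 fell and 3 were not called, the same adjusted over the list alone, with a median of 0.41. FAS2 rose by 0.65 and FAS1 by 0.50, both subunits of fatty acid synthase, and ERG20 was at 0.06. Of 60 amino acid biosynthesis genes 37 rose, 3 fell and 20 were not called, with a median of 0.29 (0.17 with the median ratio scaled to 1), and adjusted over the list alone 39 rose and 3 fell. LEU1 rose by 0.79, CYS3 fell by 0.20 and ILV5 was at -0.12. Camera's adjusted p was 0.0354 for lipid synthesis and 0.00741 for amino acid biosynthesis. The adjusted p = 0.5995 and 0.507 with an estimated correlation. Without the mixture as a block the camera adjusted p was 0.0765 and 0.143, so neither list was then called. Lipid synthesis was also not called without the rtn1 mixture (median 0.43, camera adjusted p = 0.0538), at a mean of at least 50 RPM (0.0503), without the first 50 and last 5 codons (0.0556), among genes above 0 in all libraries (0.0563) or with the median ratio scaled to 1 (0.0554). CYS3 lost its limma call without the bat1 mixture (adjusted p = 0.0644) or the tal1 mixture (adjusted p = 0.0523).

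Several lists with medians above that of all genes were not called. Of 8 subunits of the chaperonin TRiC 5 rose, 0 fell and 3 were not called, with the same count adjusted over the list alone (median 0.29, camera adjusted p = 0.132). CCT7 rose by 0.75 and CCT8 by 0.43, and CCT6 was at -0.03. Of 21 mitochondrial matrix proteins 15 rose and 4 fell, also adjusted over the list alone, and 2 were not called (median 0.28, camera adjusted p = 0.0766). KGD1 rose by 0.82 and HSP60 by 0.48, while HSP10 fell by 0.64 and SSC1 by 0.21. SSC1 lost its limma call with any 1 mixture left out (adjusted p of 0.0507 to 0.0794). Of 20 vesicle coat subunits 14 rose, 3 fell and 3 were not called, and adjusted over the list alone 15 rose and 3 fell (median 0.26, camera adjusted p = 0.0766). SEC23 rose by 0.74 and COP1 by 0.57.

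Membrane and secretory proteins differed between mixtures. Of 33 plasma membrane and vacuole transporters 6 rose, 0 fell and 27 were not called, and adjusted over the list alone 2 rose and 0 fell (median 0.28, camera adjusted p = 0.0827). Their medians were 0.54, -0.14, 0.14 and 0.68 in the tal1, pmt1, rtn1 and bat1 mixtures. PDR5, a drug efflux pump, rose by 0.72, YCF1 by 0.88 and the proton pump PMA1 by 0.49, and FCY2 was at 0.00. Without the pmt1 mixture the list was called (median 0.42, camera adjusted p = 0.00457), as it was with the median ratio scaled to 1 (0.0352), while without the bat1 mixture it was not (median 0.15, camera adjusted p = 0.338). With all 4 mixtures the adjusted p = 0.942 with an estimated correlation. YCF1 lost its limma call without the rtn1 or bat1 mixture (adjusted p of 0.0575 and 0.0576), and PMA1 without the tal1, rtn1 or bat1 mixture (adjusted p of 0.0522 to 0.0651). Of 47 ER membrane proteins 9 rose, 9 fell and 29 were not called, and adjusted over the list alone 7 rose and 8 fell. Their median was 0.14 while camera's direction was down relative to the other genes (camera adjusted p = 0.745). In the same order of mixtures their medians were 0.33, -0.18, -0.07 and 0.47, and leaving out 1 mixture gave 0.05 to 0.25. HMG1 rose by 0.75, ERG1 by 0.59 and ERG11 by 0.49, and SBH1 fell by 0.90. ERG11 lost its limma call without the tal1, rtn1 or bat1 mixture (adjusted p of 0.0646 to 0.102). Of 42 secreted, cell wall and lumenal proteins 14 rose, 6 fell and 22 were not called, and adjusted over the list alone 13 rose and 6 fell (median 0.16, camera adjusted p = 0.662). Their medians were 0.29, -0.01, -0.03 and 0.27 in the 4 mixtures, and the list median was 0.06 without the tal1 mixture and 0.09 without the bat1 mixture. UTR2 rose by 0.55, and TIP1 fell by 0.62, HSP150 by 0.36 and CCW12 by 0.34. CCW12 lost its limma call without the rtn1 or bat1 mixture (adjusted p of 0.0575 and 0.0550).

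The remaining lists held members that went both ways, and camera called none of them. Of 46 ribosome biogenesis genes 20 rose, 12 fell and 14 were not called, and adjusted over the list alone 21 rose and 12 fell (median 0.15, camera adjusted p = 0.913). SOF1 rose by 0.64 and REA1 by 0.53, NHP2 fell by 0.75, and RRP5 was at 0.03. Of 22 cytoskeleton genes 9 rose and 6 fell, also adjusted over the list alone, and 7 were not called (median 0.13, camera adjusted p = 0.834). MYO1 rose by 0.89 and ACT1 by 0.56, and TPM2 fell by 0.77. Of 14 mitochondrial carriers 3 rose, 1 fell and 10 were not called, and adjusted over the list alone 0 passed limma's threshold (median 0.07, camera adjusted p = 0.996). The median of carriers was 0.13 without the tal1 mixture and also at a mean of at least 50 RPM. GGC1 rose by 0.27 and OAC1 by 0.25, and PET9 fell by 0.12. These 3 calls were lost without the rtn1 or bat1 mixture (limma adjusted p of 0.0510 to 0.146), and that of PET9 also without each of the others.

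Of 19 aminoacyl-tRNA synthetases 7 rose and 4 fell, also adjusted over the list alone, and 8 were not called (median 0.03, camera adjusted p = 0.913). CDC60 rose by 0.50 and SES1 fell by 0.32. Of 32 proteasome genes 7 rose and 8 fell, also adjusted over the list alone, and 17 were not called (median 0.01, camera adjusted p = 0.337). RPT6 rose by 0.71, RPN9 fell by 0.56, and RPN1 was at 0.07. With the median ratio scaled to 1, the medians of carriers, synthetases and proteasome were -0.05, -0.09 and -0.11. The median of synthetases was 0.012 without the pmt1 mixture, and that of the proteasome was 0.019 without the pmt1 and 0.0054 without the rtn1 mixture. Of 67 mitochondrial ribosomal proteins 9 rose, 15 fell and 43 were not called, and adjusted over the list alone 9 rose and 12 fell (median -0.03, camera adjusted p = 0.0766). MRPS18 rose by 0.29. Without the pmt1 mixture this list was called lower (camera adjusted p = 0.0465). With all 4 mixtures the adjusted p = 0.413 with an estimated correlation, and the median was 0.22 without the first 50 and last 5 codons.

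Of 19 glycolysis and fermentation genes 3 rose and 6 fell, also adjusted over the list alone, and 10 were not called (median -0.04, camera adjusted p = 0.0766). With the median ratio scaled to 1 the list was called lower (camera adjusted p = 0.0323), and before scaling the adjusted p = 0.583 with an estimated correlation. PFK1 rose by 0.80 and CDC19 by 0.25, ENO2 fell by 0.40, and PDC1 was at -0.02. CDC19 lost its limma call without the rtn1 mixture (adjusted p = 0.0515). Of 24 RNA polymerase subunits 7 rose and 8 fell, also adjusted over the list alone, and 9 were not called (median -0.04, camera adjusted p = 0.142). RPA190 and RPA135 rose by 0.73 and 0.56, and RPC19 fell by 0.73. Of 34 translation factors 10 rose, 14 fell and 10 were not called, and adjusted over the list alone 11 rose and 16 fell (median -0.07, camera adjusted p = 0.0766). SUI2 rose by 0.70 and YEF3 by 0.31, and SUI1 fell by 0.76 and EFB1 by 0.26. Without the pmt1 mixture, or with the median ratio scaled to 1, the list was called lower (camera adjusted p of 0.0464 and 0.0429). With all 4 mixtures the adjusted p = 0.5995 with an estimated correlation, and without the rtn1 mixture YEF3 was not called by limma (adjusted p = 0.0661). Of 33 respiratory chain and ATP synthase genes 8 rose and 11 fell, also adjusted over the list alone, and 14 were not called (median -0.09, camera adjusted p = 0.0766). ATP2 rose by 0.59, and ATP1 was at 0.04. Of 8 peripheral V-ATPase subunits 2 rose, 5 fell and 1 was not called, the same adjusted over the list alone (median -0.22, camera adjusted p = 0.0940). VMA1 and VMA2 rose by 0.33 and 0.29, calls that were lost when the median ratio was scaled to 1 (limma adjusted p of 0.0638 and 0.0544), and VMA10 fell by 0.74. Leaving out 1 mixture moved the median of glycolysis to -0.066 (without rtn1), of RNA polymerase to -0.069 (without pmt1) and of the respiratory chain to -0.049 (without tal1). Without the first 50 and last 5 codons, the medians were 0.08 for glycolysis, 0.10 for RNA polymerase, 0.09 for translation factors and 0.22 for the respiratory chain.

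**Figure D3:**
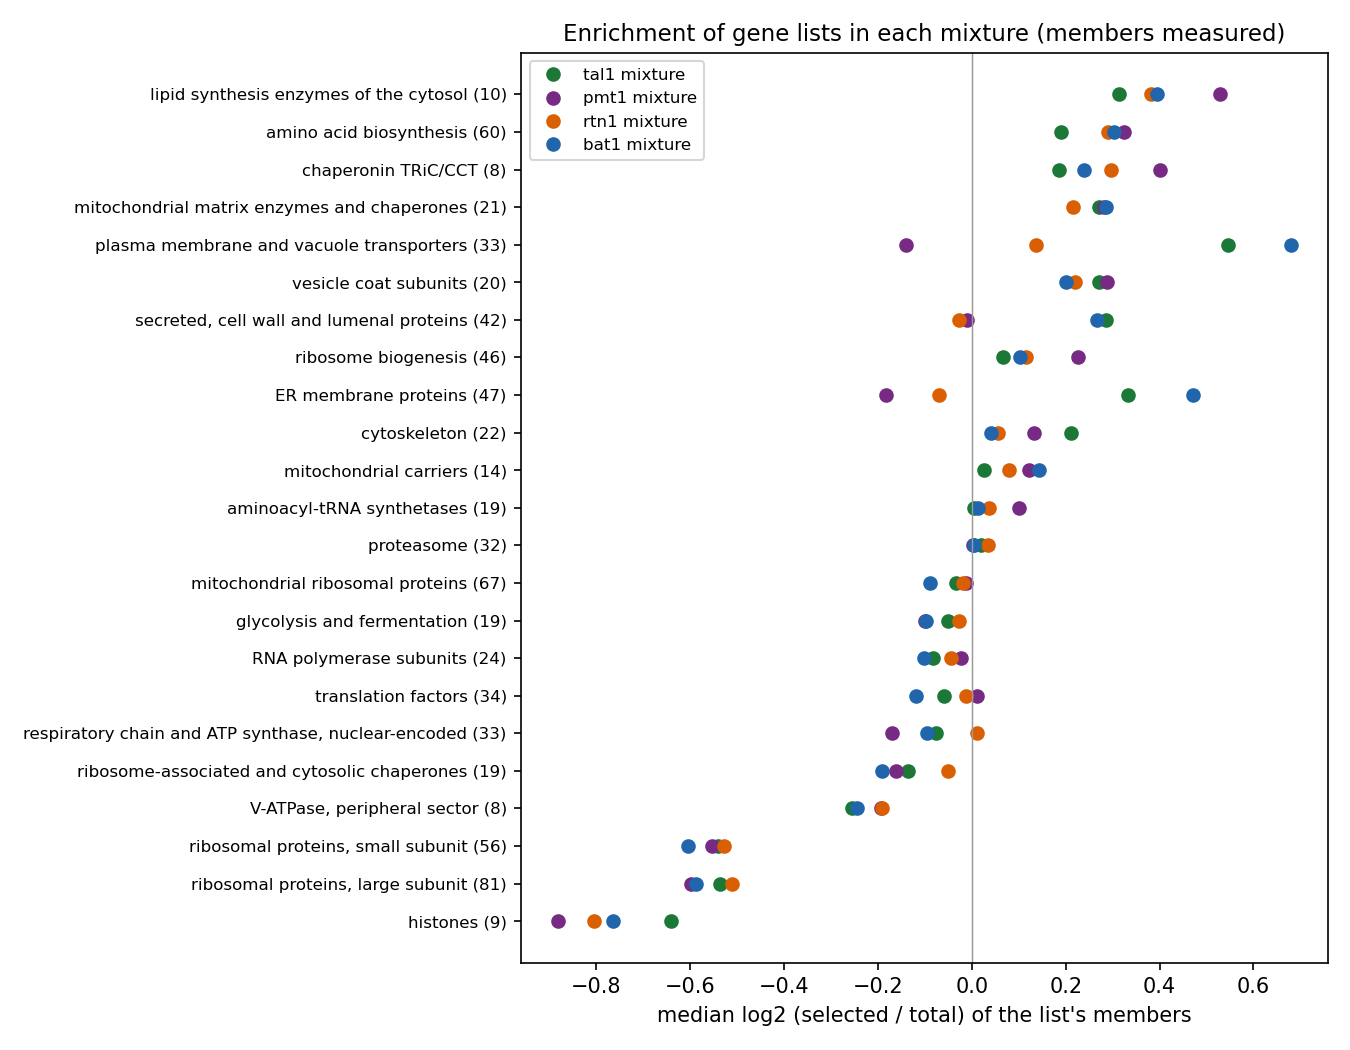
Median log2 ratio of selected to total over the measured members of 23 gene lists, with 1 point per mixture. Histones and ribosomal proteins lie lowest (medians -0.78, -0.57 and -0.56), and ER membrane proteins and transporters lie lower in the pmt1 and rtn1 mixtures than in the others, from 0.68 in the bat1 mixture to -0.14 in the pmt1 mixture for transporters.

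The first part of the coding sequence was depleted from the selected libraries in every mixture. Over 1503 genes, the log2 ratio in codons 1 to 30 minus that in codons 61 to 200 was -0.51, -0.80, -0.74 and -0.65 in the tal1, pmt1, rtn1 and bat1 mixtures, a mean of -0.68 ± 0.13 (SD, n = 4). The two-sided exact sign-flip permutation p was 0.125, the smallest that 4 mixtures can give. By window, the ratio was -0.76 ± 0.15 in codons 1 to 30, -0.75 ± 0.11 in codons 31 to 60, -0.30 ± 0.03 in codons 61 to 100 and 0.01 ± 0.02 beyond codon 100, up to codon 200. In amino acid biosynthesis genes the start difference was -1.02 ± 0.22 (SD, n = 4), in ER membrane proteins -0.94 ± 0.13, in transporters -0.60 ± 0.11 and in aminoacyl-tRNA synthetases -0.60 ± 0.16, all without genes that have a gap. In ribosomal proteins it was -0.24 ± 0.06 over 22 large-subunit genes and 0.13 ± 0.08 over 15 small-subunit genes, the latter above 0 in 4 of 4 mixtures. Codon positions are uncertain where an intron lies within the span. Of the 1503 genes 88 had 20 codons in a row at 0 in all libraries, 44 of them among 81 ribosomal protein genes, whose introns are not in the gene table; without the 88 genes the mean was -0.72.

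**Figure D4:**
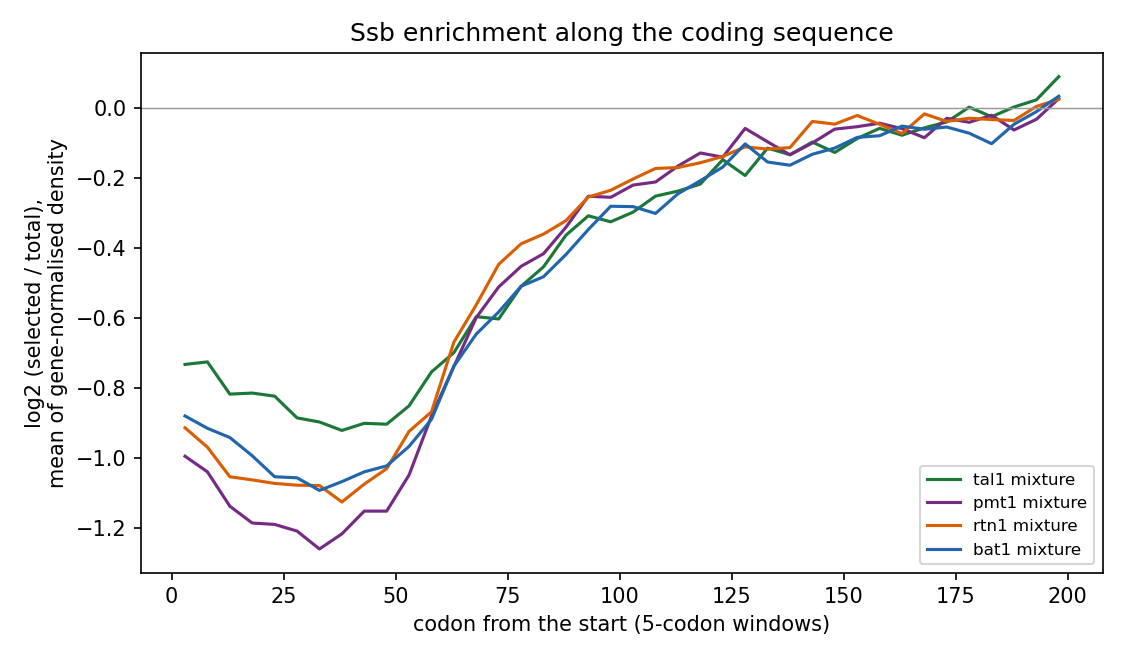
Log2 ratio of selected to total footprint density in 5-codon windows over the first 200 codons, with 1 line per mixture, each gene's density divided by its mean before averaging over the 1415 genes without a gap. All 4 lines lie lowest within the first 60 codons, with a mean of -1.08 in codons 36 to 40, and rise to a mean of 0.04 in codons 196 to 200.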

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

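A screen of 146 sets of 4 values, 1 per mixture, found 9 in which 1 mixture lay apart from the others by Dixon's criterion. Chance gives about 1 in 20, and the count of 9 is near that share. The deleted gene BAT1 was among the 9, with a log2 ratio of selected to total of -0.017 in the bat1 mixture and 0.43 to 0.49 in the others. SSB2 in the selected libraries was at 17.3 RPM in the bat1 mixture and 34.6 to 37.9 RPM in the others. The cell wall gene UTR2 had a log2 ratio of 0.35 in the rtn1 mixture against 0.61 to 0.62. MRPS18 was at 0.43 in the rtn1 mixture against 0.23 to 0.26, and the carrier GGC1 at 0.45 in the bat1 mixture against 0.18 to 0.22. In the pmt1 mixture PDC1 was at -0.10 against -0.01 to 0.01, and RPC19 at -0.86 against -0.69 to -0.67. In the tal1 mixture HTB1 was at -0.62 against -0.72 to -0.71, and CLC1 at -0.89 against -1.08 to -1.06.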

How the results depend on the processing

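The comparison with genes above 0 in all libraries, the scaled list medians, the filter on gaps, the comparison within a compartment and the profile and start alternatives were chosen after the values were seen. Over 110 named genes, 1315 of 1427 alternative values kept their direction and side of the threshold, 66 lost the call, 32 gained it and 14 reversed. Over 23 lists the counts were 223 of 252, with 13 lost, 6 gained and 10 reversed. Without the mixture as a replicate block, 2099 genes were called, 1999 of them shared with the 2290 of the blocked fit. Without the block 4 lists were called in place of 6, and with an estimated correlation 0 were called. With the median ratio scaled to 1, camera also called transporters higher (adjusted p = 0.0352) and glycolysis (0.0323) and translation factors (0.0429) lower, and lipid synthesis was not called (0.0554).

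Leaving out 1 mixture gave a mean index of 0.697 to 0.797 and a profile difference of -0.239 to -0.129 and a start difference of 0.54 to 0.58, and 3 mixtures cannot pass the threshold in these tests. Without the first 60 codons the profile difference was -0.239 and no longer passed. At a mean of at least 50 RPM, 1511 genes were called, 934 of them higher, because 2131 genes were tested. With the median ratio scaled to 1, 953 genes were higher. This scaling reversed the medians of mitochondrial carriers to -0.052, aminoacyl-tRNA synthetases to -0.089 and the proteasome to -0.11. It also reversed RPN1 to -0.054, ERG20 to -0.0667, ATP1 to -0.085, RRP5 to -0.094 and FCY2 to -0.12, none of them called before or after.

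Without the first 50 and last 5 codons, medians reversed to 0.22 for mitochondrial ribosomal proteins and the respiratory chain, 0.077 for glycolysis, 0.099 for RNA polymerase, 0.093 for translation factors and 0.0066 for chaperones. The respiratory chain also reversed to 0.037 at 50 RPM, where fewer members were tested. PDC1 reversed to 0.077, CCT6 to 0.051 and HSC82 to 0.010 without these codons, also when genes above 0 in all libraries were used. Leaving out 1 mixture, FCY2 ran from -0.12 to 0.11 and PDC1 from -0.037 to 0.000522. Leaving out the first 50 codons removed only part of the depleted start of the coding sequence, since codons 61 to 100 still had a mean log2 ratio of -0.30. The cause of these reversals was not tested. Subtraction of background and the count tests were not run. Depth limits genes below 6.07 to 14.5 RPM, which are listed at 0.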

Other observations

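The length classes and the tests on the deleted genes, on SSB2, on membrane proteins and on other splits of the libraries were chosen after the results were seen. Enrichment followed the length of the coding sequence in genes other than those of the ribosome. The 71 genes of up to 100 codons had a median log2 enrichment of -0.78, and 94.4% of them were called lower by limma. The 352 genes of 100 to 200 codons had a median of -0.34 (59.9% lower) and the 1102 genes of 200 to 400 codons a median of 0.04 (22.2% lower). The 1505 genes of 400 to 800 codons had a median of 0.25 (9.57% lower) and the 758 longer genes 0.39 (5.15% lower). Without the first 50 and last 5 codons the order was the same, from -0.67 in the shortest class to 0.44 in the longest. Depletion went on beyond codon 50, with a mean of -0.30 in codons 61 to 100. This setting therefore does not separate length from the depleted start. The gene lists were not compared with genes of like length, so their calls are not separated from length either.

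Footprints of the deleted genes reached their own selected libraries. Binding of Ssb1-GFP after lysis at the positions used in the tagged cells may account for them, and the tests did not decide this. Relative to the rest of the gene, codons 1 to 60 were less depleted in the own mixture by 0.56, the furthest from 0 of 24 assignments. With codons 1 to 30 the difference was 0.48, again the furthest. A lower ratio in the rest of the gene gives such a difference too, so it says nothing about binding within the start itself. The slope of the own profile differed from that of the other mixtures by -0.580 over whole genes, the lowest of 24. Without the first 60 codons the difference was -0.498 and 2 of 24 were as low. Ribosomes carried through the purification without Ssb would give a flat profile, and the mean slope was 0.527, but a profile common to all libraries gives a slope above 0 too, so this stays open. For PMT1 and RTN1 the shift of ER membrane proteins in the same mixtures adds to the difference, and no biological explanation was tested.

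SSB2 was nearly absent although the untagged cells are described as wild type. Reads shared with SSB1 are argued against as the cause, since at codons where SSB1 has reads SSB2 reached at most 1.03% of SSB1. A small share of untagged cells is argued against by the deleted genes, whose own total levels were at least 56.4% of those in the other mixtures. Untagged cells without a working SSB2 may account for it, as the highest level in 8 libraries was 37.9 RPM, but a low level of SSB2 in cells that carry it cannot be told apart from this.

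ER membrane proteins, transporters and secreted proteins had higher ratios of selected to total in the tal1 and bat1 mixtures than in the pmt1 and rtn1 mixtures. The gap between the ER list medians was 0.527, with 40 of 46 members in that direction. Total libraries of the tal1, pmt1, rtn1 and bat1 mixtures deviated from the ER list's mean by medians of -0.21, 0.03, 0.22 and -0.04. Selected libraries deviated by -0.02, -0.25, 0.06 and 0.18. The tal1 and rtn1 mixtures thus stood apart mainly through their total libraries, and pmt1 and bat1 through their selected ones. Scaling left a gap of 0.462, which argues against scaling. Before scaling, depletion of large-subunit ribosomal proteins in the pmt1 and rtn1 mixtures was 98.8% of that in the others. After it, their medians were -0.70 and -0.59 in the pmt1 and rtn1 mixtures, against -0.71 and -0.72 in tal1 and bat1. Small-subunit medians were then -0.65 and -0.61 against -0.72 and -0.74. A much weaker purification is argued against, but a slightly weaker one stays open. PMT1 and RTN1 both encode ER membrane proteins, so loss of such a protein in the tagged cells could be a biological cause. For the ER list the other pairings of the mixtures gave a gap of at most 0.128, and for transporters at most 0.205 against 0.616, but 4 mixtures allow 3 pairings, too few for a permutation share under 0.05, no other test was run on a pairing chosen after its values were seen, and a batch shared by the same mixtures cannot be told apart from this.

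Of the 35 splits of the 8 libraries without a block, 1 called as many genes as selected against total (2099). The highest other called 0 with limma and 434 at an unadjusted p under 0.05. Every other split has selected and total libraries in both arms, which widens the spread within an arm. These splits also ignore the pairing within a mixture, so they do not exclude chance as the source of that count. With the mixture as a block, 1 of 8 splits called as many (2290), and the highest other called 0, with 99 at an unadjusted p under 0.05; 8 splits are too few for a share under 0.05. For gene lists without a block, 33 of 35 splits called as many as the 4 of the real split, up to 13, so chance is not excluded for that count. With the block, 3 of 8 splits called as many as the real 6, up to 10, and 8 splits are too few for a share under 0.05.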
